A study of Mus musculus with 2 samples.

How the data were processed

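Binding of the transcription factor Sox4 was profiled by chromatin pull-down and sequencing in mouse (C57BL/6) progenitor B cells that came from embryonic fetal liver. Per the labels, these cells had been transduced in turn with retroviruses encoding the biotin ligase BirA, the p190 form of the Bcr-Abl oncogene, a Cre construct and Sox4 carrying a BAP tag, and had been sorted after each step. Per the labels' protocols, sonicated chromatin was captured on streptavidin beads, although the antibody field of the labels reads SOX4. The series holds 1 bioChIP library and 1 input library, so nothing here has a replicate check, and no p-value was computed between conditions.

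Per the submitters' processing notes, Bowtie 0.12.8, MACS 1.4.2 and the mm9 genome build were used. The notes list these names without parameters. The deposited list holds 8730 peaks of the bioChIP library. Whether they were called against the input library is not given in the sources used here. MACS 1.4 can also take the background from the pull-down library itself, and the list has no false discovery rate, a column it writes when a control is given. A separate file of the input library was not used here. The sequencing depth of both libraries is not given in the sources used here, so no value could be scaled to it.

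Each peak has 4 kinds of values. The deposited tag number is a whole-number count of reads per peak and was not normalized. The deposited fold is a linear ratio of tags in the peak to the background that the peak caller expected, from whichever library supplied it. The deposited score was read as minus 10 log10 of the peak's p-value, since the lowest score lies just above 50, which is the usual MACS threshold of 1e-05, and 7 peaks reached 3100 or more. Other deposited columns give positions in bp and distances in bp to the start (TSS) and end (TES) of RefSeq transcripts, with 0 where the peak interval overlaps the site. The tool behind this annotation is not given in the sources used here. Tested on the list itself, the promoter class ran from -4938 to 490 bp around a TSS, and genes were listed only when the peak lay in them or within 25 kb of either end. Positions are printed as the list gives them, and whether starts were counted from 0 or 1 was not stated.

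Genes were counted as follows. The list names 15228 transcripts, of which 14992 matched the mouse RefSeq gene table (assembly GRCm38.p6) by accession, 192 by symbol and 32 by an older symbol, and 12 did not match. That table was used for names, gene class, chromosome and gene length, and none of its coordinates were used. The background was the 20953 protein-coding genes with an NM accession on chromosomes 1 to 19 and X. Some of these genes entered RefSeq after the deposited annotation was made and could then not have been listed. A gene had a promoter peak when a peak interval lay within 5 kb of the TSS of any of its transcripts, and a gene-body peak when an interval lay in the gene or within 10 kb of it. The plan had been to measure from summits. The distances deposited run from the peak interval, so the interval was used, and the summit and midpoint versions could not be made.

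Before the data were examined, 13 gene lists, some of the alternatives and a rule for the genes to be named were fixed. The lists were V(D)J recombination, B-lineage transcription factors, pre-BCR and B-cell surface or signalling genes, Wnt/beta-catenin signalling, cell cycle and survival, the SOX family, chromatin regulators, T-lineage, myeloid, erythroid and hepatocyte genes, ribosomal protein genes and olfactory receptors. All members matched the gene table. Lef1 stands in both the B-lineage and the Wnt list, and Tcf7 in both the Wnt and the T-lineage list. Kinase and binding-protein genes whose symbols resemble those of ribosomal proteins were left out of that list. The named genes were Rag1, Rag2, Csnk1e and Sox4, up to 4 members per list with the highest score (promoter peaks first), the 10 highest peaks overall and the 5 genes with most peaks. Ribosomal protein and olfactory receptor genes were summarised only. List members named beyond this rule, such as those without a peak, were chosen after their values were seen. One gene that the rule names is not reported here.

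Each list's count was set against 10000 random gene lists of the same size and the same make-up by gene-length decile (10 classes). The mean and the central 95% range of the random counts are given as a description of this library, because genes are not replicates. For peak strength, random sets of promoter-peak genes were drawn without matching on gene length. There each gene entered with its highest score and its highest fold among its promoter peaks. Shares have exact Clopper-Pearson 95% intervals and tag counts exact Poisson 95% intervals. Both cover counting error only, and PCR duplicates or the spread between cultures are not in them. The list procedure was tested on simulated data in 20 sets. Each of the 20953 genes drew a peak independently, at the rate of its length decile. The random lists rest on the same model, so this checks the procedure only. Peaks shared by neighbouring genes were not simulated. Of the unchanged lists, 4.62% fell outside the range. Of the lists given 2 times the usual rate, 84.2% lay above it (95.8% of those with 20 or more members), with a median ratio of 2.01. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

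The alternatives fixed beforehand included peaks with a fold of 10 or more, the 4365 peaks with the higher scores and other TSS windows. They also included random lists not matched on length and merging of peaks within 1 kb. Further alternatives were chosen after seeing the data. These gave each peak to its closest gene only or used a gene-body flank of 25 kb. Others used the deposited promoter class or left out the 2 peaks with a fold under 2.2. The deposited list has no false discovery rate, so the planned threshold of 5% was not applied, and the planned flank of 50 kb exceeds what the list annotates. No genome sequence of the mm9 build was used here, so the planned motif and 7-mer counts, random genome positions and peaks per Mb were left out.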

Results

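The deposited data come from a pull-down of tagged Sox4 from chromatin of Bcr-Abl-immortalized progenitor B cells. Sox4 is an HMG-box transcription factor needed for early B-cell development. The series pairs 1 streptavidin pull-down library (Sox4 bioChIP) with 1 input chromatin library. The title of the series names the RAG genes and the gene of casein kinase 1 epsilon, so the questions the design poses are where Sox4 lay relative to genes in general, and whether these loci were among the bound ones. The peak list held 8730 peaks with a median width of 911 bp (quartiles 759 and 1168 bp). They contained a median of 71 tags each (quartiles 53 and 100) and 763284 tags in all. The median fold over background was 4.43 (quartiles 3.76 and 5.42), and 383 peaks reached a fold of 10 or more. Scores, fold values and tag counts of peaks are the authors' own throughout, from this 1 library, and rank peaks within this list only. No pull-down without tagged Sox4 was analysed here and no motif was counted. A peak therefore does not by itself show that Sox4 was bound there.

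Sox4 peaks lay mainly at the starts of genes. Of the 8730 peaks, 6026 were within 1 kb of an annotated TSS (69.0%, exact 95% interval 68.0 to 70.0%), and 5545 overlapped one. In the deposited position classes, 6171 peaks (70.7%, 69.7 to 71.6%) were promoter peaks, 841 (9.63%) were intronic, 471 (5.40%) lay upstream beyond the promoter, 285 (3.26%) were exonic, 271 (3.10%) lay downstream and 204 (2.34%) lay at the TES. For 487 peaks (5.58%, 5.11 to 6.08%) no gene was listed, which means none within 25 kb. Promoter peaks had a median score of 116.8 and a median of 77 tags. The medians of the other classes ran from 73.8 to 85.5 for the score and from 57 to 59 for tags. Promoter peaks were also wider (median 980 bp, against 785 to 848 bp in the other classes), and tags were counted over the whole peak. The median fold was 4.44 for promoter peaks, 4.44 for intronic peaks, 4.5 for peaks without a listed gene, 4.37 upstream, 4.31 downstream, 4.08 at the TES and 4.0 for exonic peaks. A fold of 10 or more was reached by 4.15% of promoter peaks (3.66 to 4.68%). It was reached by 5.71% of intronic peaks (4.24 to 7.50%) and 6.57% of peaks without a listed gene (4.54 to 9.15%). For exonic peaks it was 2.81% (1.22 to 5.46%) and for TES peaks 2.94% (1.09 to 6.29%). Each of these intervals overlaps that of promoter peaks, which does not show that the shares are equal. The share at promoters depended on the peaks retained: it was 78.1% among the 4365 peaks with the higher scores and 66.6% among the 383 with a fold of 10 or more.

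**Figure D1:**
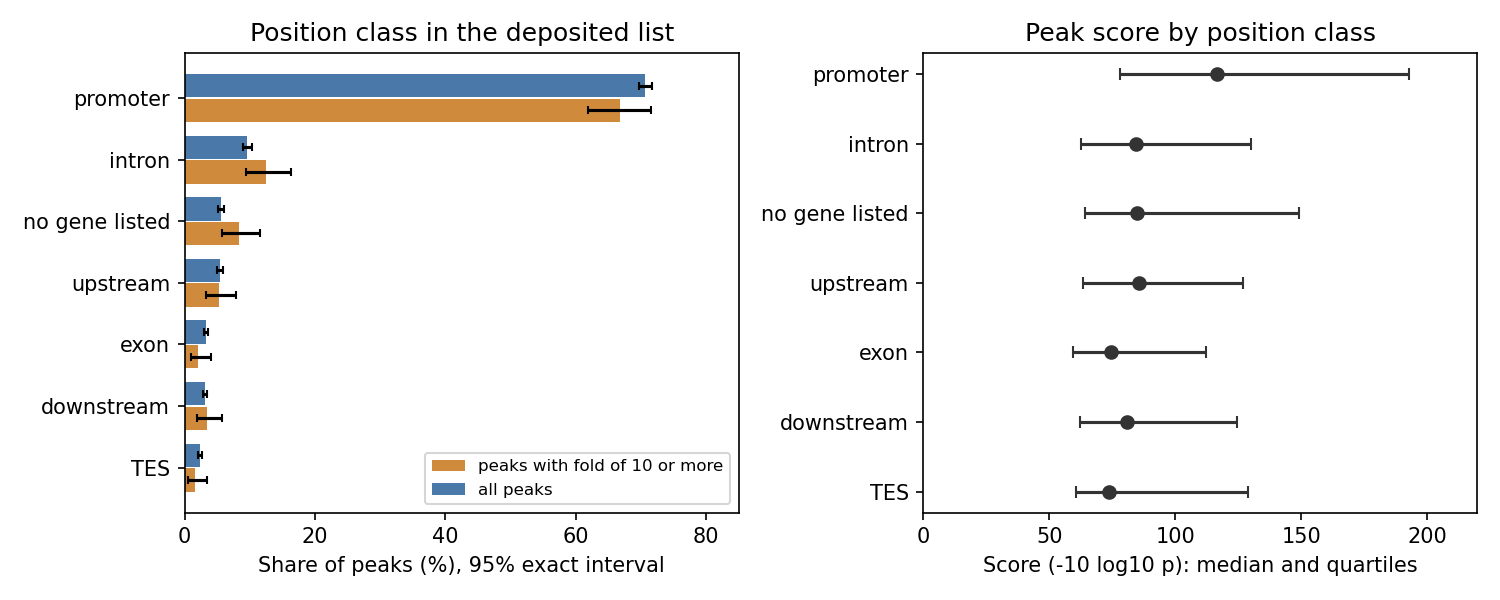
Left, share of peaks (percent) in each position class of the deposited list, for all 8730 peaks and for the 383 with a fold of 10 or more; bars start at 0 and whiskers are exact 95% intervals. Right, median score (minus 10 log10 p, points) with quartiles (whiskers) per class. Promoter peaks made up 70.7% of all peaks and 66.8% of those with a fold of 10 or more, and had the highest median score, 116.8.

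Of the 20953 protein-coding genes examined, 6875 (32.8%) had a promoter peak and 8540 (40.8%) had a peak in the gene or within 10 kb. Genes were reached unevenly across chromosomes. Chromosome 11 held the most peaks, 797 (9.13%), and 40.9% of its genes (38.5 to 43.4%) had a promoter peak. Chromosome X held 92 peaks (1.05%, 0.85 to 1.29%), and 70 of its 905 genes had a promoter peak (7.73%, 6.08 to 9.67%), against 33.9% (33.3 to 34.6%) of the 20048 autosomal genes. Peaks on chromosome X held a median of 56 tags at a median fold of 4.56, compared with 71 tags and 4.42 on the autosomes. The labels do not give the sex of the cells.

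Of the genes that the title names, Csnk1e had a strong promoter peak, Rag1 a moderate one just inside the gene, and Rag2 none near its start. Csnk1e encodes casein kinase 1 epsilon, a kinase of the Wnt pathway. Its TSS was covered by a peak on chromosome 15 from 79271644 to 79272809 (mm9; transcript NM_013767) with 157 tags (exact 95% interval 133 to 184), a fold of 9.40 and a score of 452.8, which ranked 479 of 8730. A weaker peak lay 7147 bp upstream (70 tags, 54.6 to 88.4, fold 2.95, score 54.6). A further peak was listed 14193 bp past the TES of Csnk1e, but it covered the TSS of Tmem184b (62 tags, fold 4.17). Rag1 encodes a subunit of the recombinase that rearranges immunoglobulin genes. Its peak on chromosome 2 from 101488418 to 101489179 (mm9; NM_009019) began 510 bp inside the gene, in an intron by the deposited annotation. It held 57 tags (43.2 to 73.9) at a fold of 5.11, and its score of 102.7 exceeded that of 48.8% of all peaks. Rag2 encodes the partner subunit. It was listed for this same Rag1 peak, which lay 15734 bp past the TES of Rag2 and 23514 bp from its TSS (NM_009020), and for no other. The next peak on one side of the Rag1 peak lay 29.0 kb away and was assigned to Traf6, and the next on the other side lay 7210 kb away and was assigned to Api5.

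The Sox4 gene itself had peaks on either side of the transcript and none over it. One lay 4074 bp upstream of the TSS (chromosome 13, 29049624 to 29051080; NM_009238) with 104 tags (84.98 to 126) at a fold of 3.73 and a score of 141.1. The other lay 7381 bp past the TES with 43 tags (31.1 to 57.9) at a fold of 4.38 and a score of 67.3. The cells had received a Cre construct and retroviral tagged Sox4, and the state of this locus was not examined.

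**Figure D2:**
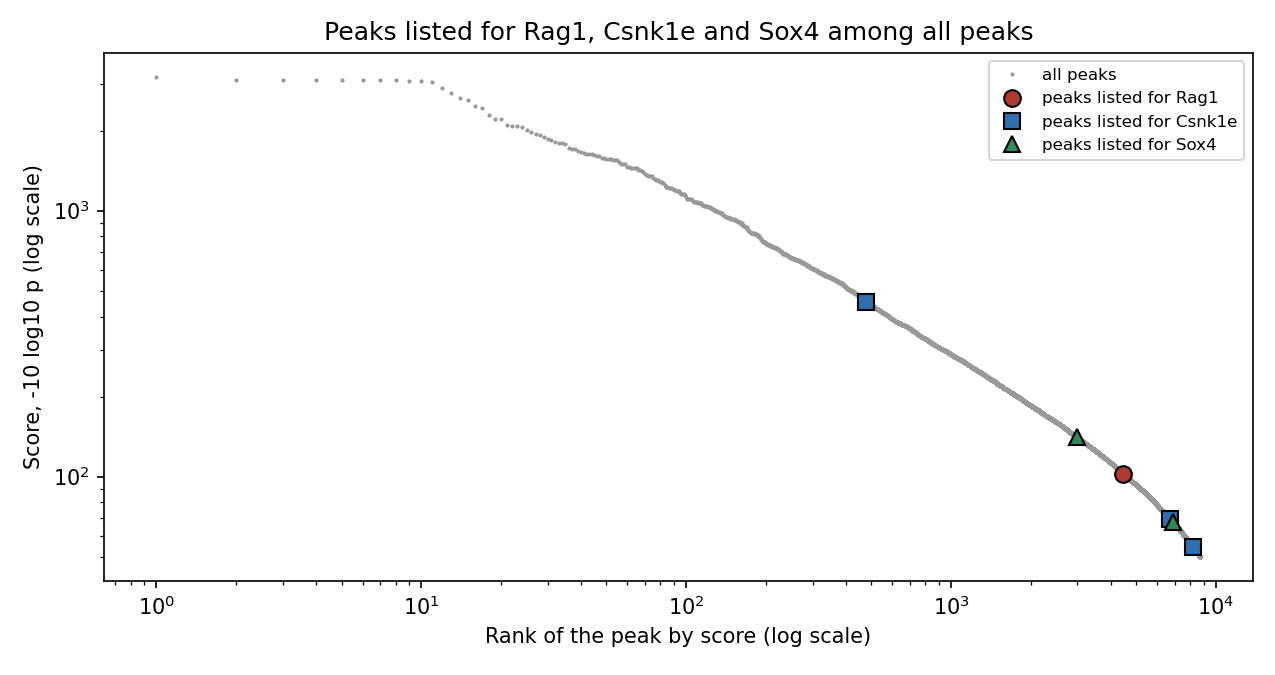
Score (minus 10 log10 p, log scale) of all 8730 peaks against their rank by score (log scale), with the peaks listed for Rag1 (circle), Csnk1e (squares) and Sox4 (triangles). The promoter peak of Csnk1e ranked 479, the Sox4 upstream peak 2978 and the Rag1 peak 4473.

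Genes of V(D)J recombination, the joining of immunoglobulin gene segments, had promoter peaks in 9 of 12 cases (75%, 42.8 to 94.5%). Length-matched random lists held a mean of 4.30 such genes with a 95% range of 1 to 8. The highest score belonged to Xrcc5, which encodes the Ku80 subunit of the end-joining machinery (chromosome 1, 72353434 to 72354456; 188 tags, fold 20.2, score 916.4). Xrcc6, encoding the other Ku subunit, followed with a fold of 3.78 and a score of 154.9. The end-joining gene Nhej1 had a fold of 5.09 and a score of 143.2. The peak counted for Prkdc, the DNA-dependent protein kinase, had a fold of 4.31 and a score of 111.6, and it covered the TSS of Prkdc and that of Mcm4. Besides Rag2, the genes Dntt, which encodes terminal transferase, and Dclre1c, which encodes Artemis, had neither a promoter nor a gene-body peak. With each peak given to its closest gene only, a setting chosen after seeing the data, 6 of the 12 genes retained a promoter peak. That count was within the random range. The peaks of the 3 genes lost, Prkdc, Atm and Xrcc4, covered the TSS of these genes but also that of another gene, Mcm4, Npat and Tmem167, which the file names as the closest. The promoter count was also within the random range for the higher-scoring peaks (4 of 12), with a TSS window of 20 kb (9 of 12) and in the gene-body count (9 of 12, random mean 5.34, range 2 to 9). The gene-body count was above the range with random lists not matched on length (9 of 12, random mean 4.85) and with a flank of 25 kb, a setting chosen after seeing the data (11 of 12, random mean 6.21). The median score of the list's promoter peaks was 102.7, above 29.7% of random sets of 9 promoter-peak genes.

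B-lineage transcription factor genes had promoter peaks in 14 of 22 cases (63.6%, 40.7 to 82.8%; random mean 7.69, range 4 to 12). The highest score was at Tcf12, which encodes the E protein HEB (chromosome 9, 71958358 to 71960223; 246 tags, fold 9.68, score 880.7). Myb, a regulator of blood progenitors, had a fold of 8.70 and a score of 521.1. Tcf3, which encodes the E2A proteins, had a fold of 6.20, and Bcl11a a fold of 6.22 with 3 promoter peaks. A further 5 members, Ikzf3, Irf8, Pax5, Erg and Mef2c, had peaks only in the gene or within 10 kb of it, at folds of 19.2, 12.5, 4.20, 4.17 and 3.89, so that 19 of 22 had a gene-body peak (random mean 9.55, range 5 to 14). The Pax5 peak lay 5396 bp from the Pax5 TSS and was assigned to the promoter of its closest gene, 5730488B01Rik. Spi1, Bach2 and Irf4 had neither. Among the promoter peaks, the list's median score of 219.5 exceeded 99.5% of random sets of 14 promoter-peak genes, and its median fold of 4.86 exceeded 78.2% of them. The promoter count fell within the random range with a TSS window of 1 kb (12 of 22) and for the higher-scoring peaks (9 of 22).

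Pre-BCR and B-cell surface or signalling genes had promoter peaks in 14 of 19 cases (73.7%, 48.8 to 90.9%; random mean 6.18, range 2 to 10). Cd24a, which encodes the surface protein CD24, had the highest score (chromosome 10, 43297875 to 43300223; 276 tags, fold 6.67, score 569.1). Vpreb3 had a peak 961 bp from its TSS that was annotated to the TES class (fold 10.5, score 369.7). Cd79a, encoding a signalling chain of the B-cell receptor, had 2 promoter peaks. The higher-scoring one lay 4895 bp from its TSS (fold 8.41, score 299.2), and its closest gene was Arhgef1. The surrogate light chain genes Vpreb1, Vpreb2 and Igll1 also had promoter peaks, at folds of 7.35, 3.91 and 5.55. Vpreb1 had 2 promoter peaks, and the higher-scoring one, with the fold given, covered the TSS of Top3b, its closest gene. The Vpreb2 peak lay 3634 bp from the TSS in the TES class. Vpreb1 and Vpreb2 are near-identical copies, and whether reads at these peaks could be assigned to the right copy was not tested. Cd22 and Blk had no promoter or gene-body peak. With a TSS window of 1 kb, 9 of the 19 genes had a peak, which was within the random range.

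Wnt/beta-catenin genes had promoter peaks in 24 of 41 cases (58.5%, 42.1 to 73.7%; random mean 14.9, range 9 to 21). The highest score was at Gsk3b, which encodes a kinase that marks beta-catenin for destruction (fold 7.86, score 597.9), in a peak that also covered the TSS of BC031361. Csnk1e had the next highest. Lef1, encoding a beta-catenin partner on DNA, had a fold of 5.31 and a score of 407.8, and the co-receptor gene Lrp6 had a fold of 6.51 and a score of 372.2. Counted after the values were seen, all 3 casein kinase 1 genes of the list and all 3 Dishevelled genes had a promoter peak, as against 2 of the 10 Frizzled receptor genes. The beta-catenin gene Ctnnb1 had a fold of 8.05. Axin2 and Tcf7l2 had no promoter or gene-body peak. The promoter peaks of the list had a median fold of 5.36, above 99.0% of random sets of 24 promoter-peak genes, and a median score of 145.1, above 87.4% of them. In the gene-body count 27 of 41 genes had a peak (random mean 18.3, range 12 to 25), and with a flank of 25 kb the count of 28 was within the random range.

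**Figure D3:**
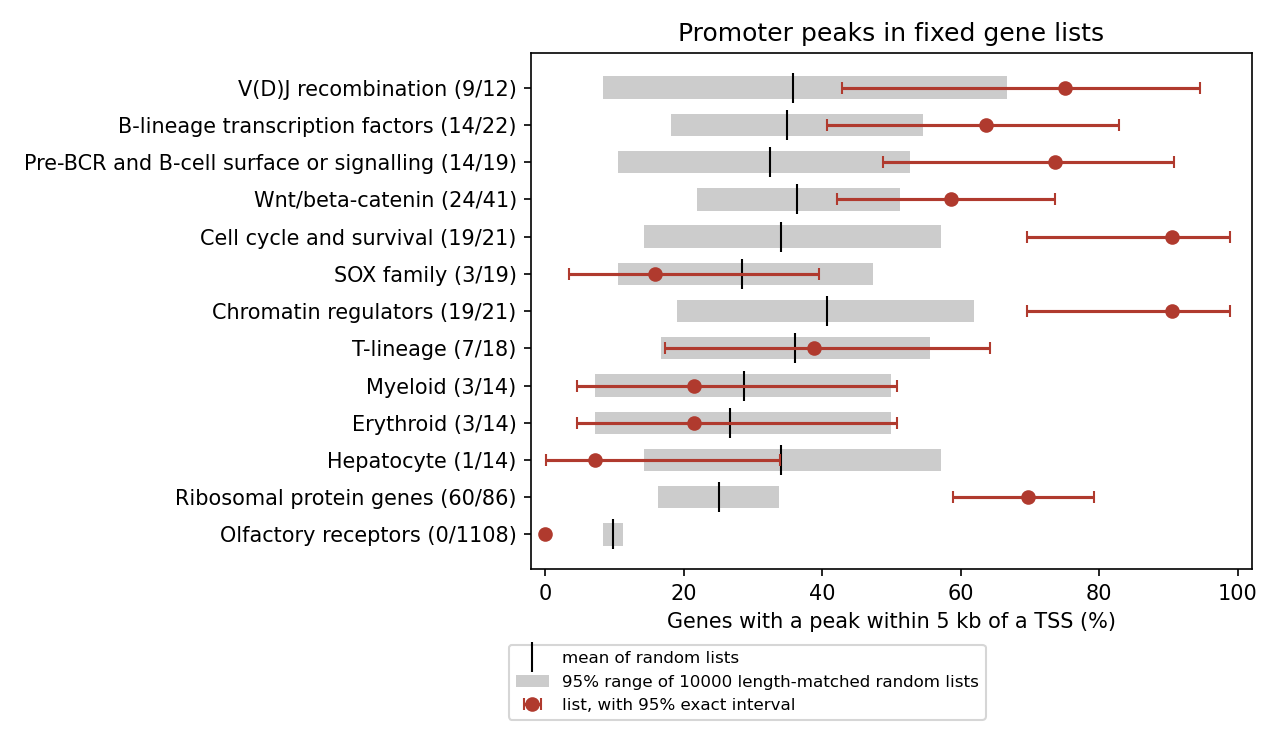
Share of genes (percent) with a peak within 5 kb of a TSS in each of the 13 gene lists (points, with exact 95% intervals; counts beside the names). Grey bars are the central 95% range and black marks the mean of 10000 length-matched random lists. The lists above their bar ran from Wnt/beta-catenin at 58.5% to cell cycle and survival and chromatin regulators at 90.5%, and hepatocyte genes and olfactory receptors lay below.

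Genes of the cell cycle and survival and genes of chromatin regulators were the most often marked of the lists. Promoter peaks were found at 19 of 21 cell cycle and survival genes (90.5%, 69.6 to 98.8%; random mean 7.16, range 3 to 12). The highest scores were at Cdk4, encoding a G1 kinase (fold 7.96, score 532.8), at Bbc3 and Bcl2l11, which encode the pro-apoptotic proteins PUMA and BIM (folds 6.46 and 6.14, scores 488.8 and 411.2), and at E2f1 (fold 8.63, score 399.9). Only Cdkn1a of this list had no promoter or gene-body peak. Promoter peaks were also found at 19 of 21 chromatin regulator genes (90.5%, 69.6 to 98.8%; random mean 8.55, range 4 to 13). Arid1a, a subunit of the BAF remodelling complex, had 478 tags, a fold of 10.4 and a score of 1623.7. Ezh2, the methyltransferase of Polycomb complex PRC2, had 354 tags, a fold of 10.8 and a score of 940.1, and all 3 PRC2 core genes counted had a promoter peak. Smarca4 and Kdm6b followed with folds of 7.48 and 5.45 and scores of 665.4 and 578.6. Tet1 and Tet3 had none. In strength, the chromatin regulator peaks had a median score of 272.9, above 99.98% of random sets, and the cell cycle and survival peaks one of 208.1, above 99.4%. Their median folds were 5.33 and 5.15, above 97.8% and 95.1% of random sets, the second within the random range of 3.93 to 5.32.

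Ribosomal protein genes, a housekeeping group, had promoter peaks in 60 of 86 cases (69.8%, 58.9 to 79.2%; random mean 21.6, range 14 to 29). Their median score of 119.5 exceeded 51.5% of random sets of promoter-peak genes. No olfactory receptor gene had a promoter peak (0 of 1108; random mean 109, range 93 to 125), and 1 had a gene-body peak.

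Genes of other blood lineages and of hepatocytes, and the SOX family, were not marked above the range of random lists. T-lineage genes had promoter peaks in 7 of 18 cases (38.9%, 17.3 to 64.3%; random mean 6.48, range 3 to 10). The highest scores were at the receptor gene Notch1 (fold 4.26, score 221.8), at Zap70 4373 bp inside the gene (fold 4.73, score 142.0), at the Notch target Hes1 (fold 2.93, score 120.5) and at Lck (fold 5.17, score 116.9). Myeloid genes had 3 of 14 (21.4%, 4.66 to 50.8%; random mean 4.02, range 1 to 7). These were Cebpb (fold 3.0, score 95.9), Prtn3 (fold 4.18, score 91.3) and Elane, whose peak was closest to Cfd (fold 3.43, score 59.2). Csf3r was counted only for a peak at the Mrps15 promoter (fold 4.85, score 73.0). Erythroid genes had 3 of 14 (random mean 3.74, range 1 to 7), namely the transferrin receptor gene Tfrc (fold 5.47, score 244.1), Klf1 (fold 4.81, score 159.6) and Nfe2 (fold 4.07, score 119.3), and none of the globin genes of the list had a peak. Hepatocyte genes had 1 of 14 (7.14%, 0.18 to 33.9%; random mean 4.76, range 2 to 8), which was below the range but within it without matching on length, for the higher-scoring peaks and for peaks of fold 10 or more. That 1 was Apoa2, counted for a peak closest to Tomm40l (fold 4.03, score 86.8), and Fgb was counted for a gene-body peak at the Plrg1 promoter (fold 3.93, score 62.3). The SOX family had 3 of 19 (15.8%, 3.38 to 39.6%; random mean 5.41, range 2 to 9). Besides Sox4 these were Sox13 (fold 3.49, score 83.3) and Sox12 (fold 3.53, score 60.6), and Sox15 was counted for a gene-body peak closest to Mir1934 (fold 6.44, score 344.3). In all, 7 of the 13 lists lay above and 2 below the random range. For lists drawn at random, 0.65 would be expected outside it. The random lists were matched on gene length but not on expression, which was not analysed here. They also draw on genes such as olfactory receptors (0 of 1108), which lowers their counts. The highest ratio of observed to random mean count was that of ribosomal protein genes (2.78). The tally therefore cannot separate a preference for these 7 lists from one for active promoters in general. With only the 383 peaks of fold 10 or more, each of these 7 lists was within the random range of the promoter count, and random lists then held a mean of at most 1.06 such genes. In the gene-body count at that setting, B-lineage transcription factors (3 of 22, random mean 0.50) and chromatin regulators (3 of 21, random mean 0.57) were above the range.

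The 10 highest peaks of the list were all promoter peaks. First by score stood Mtf2, which encodes a partner of PRC2 (chromosome 5, 108494016 to 108495200). It had 462 tags, a fold of 42.7 and a score of 3179.3. Several peaks shared a score of 3100 although their tags (407 to 1078) and folds differed, so the score orders the top peaks only loosely. The next were Zfp113 on chromosome 5 (407 tags, fold 42.5), Hspa9, a mitochondrial chaperone gene, on chromosome 18 (549 tags, fold 42.5), a start shared by Mir1893 and Epc1 on chromosome 18 (652 tags, fold 40.0), Midn on chromosome 10 (1078 tags, fold 29.6), Cox20 on chromosome 1 (766 tags, fold 29.6) and Fam60a on chromosome 6 (636 tags, fold 26.5), all with a score of 3100. Ptma, which encodes prothymosin alpha (690 tags, fold 32.9, score 3088.6), Hnrnpab, which encodes an RNA-binding protein (523 tags, fold 26.5, score 3078.7), and Trim28, which encodes the corepressor KAP1 (608 tags, fold 40.1, score 3068.6), completed the 10. The genes with most peaks in the gene or within 10 kb were Maml3, a Notch coactivator gene, with 9, Zmiz1 and the phosphatase gene Ptpn6 with 7 each, and Midn and Gse1 with 6 each. Maml3, Zmiz1 and Gse1 are over 200 kb long, while Ptpn6 spans 18.0 kb and Midn 12.4 kb. Peaks at neighbouring genes within 10 kb are included in these counts. None of these values has a replicate, and whether they would recur in a further culture was not measured.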

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

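The 208 values compared across settings include 13 gene lists counted by promoter and by gene body, and each list value below is the ratio of the observed count to the mean of random lists. With peaks of fold 10 or more, 383 peaks remained, and 66.6% of them lay within 1 kb of a TSS; chromosome X held 1.31% and chromosome 11 7.57% of them. By class they were 66.8% promoter, 12.5% intron, 8.36% without a listed gene, 2.09% exon and 1.57% TES. So few peaks leave the lists almost empty: apart from olfactory receptors, random lists then held a mean of at most 1.46 genes, so these ratios rest on few genes. The gene-body counts of B-lineage transcription factors and chromatin regulators stayed above the random range. The promoter ratio was 5.52 for V(D)J recombination, 3.42 for pre-BCR genes, 5.42 for chromatin regulators and 0 for the SOX family, T-lineage, myeloid, erythroid and hepatocyte lists. It was also 0, down from above the random range to within it, for B-lineage transcription factors, Wnt/beta-catenin, cell cycle and survival, and ribosomal protein genes. The gene-body ratio was 3.67 for V(D)J recombination, 6.01 for B-lineage transcription factors, 2.46 for pre-BCR genes, 5.29 for chromatin regulators and 0 for the SOX family, T-lineage, myeloid, erythroid, hepatocyte and olfactory lists, and also 0 and within the random range for Wnt/beta-catenin and ribosomal protein genes. With so few genes expected, a count of 0 does not show a change of direction. With the 4365 higher-scoring peaks, 78.1% lay within 1 kb of a TSS, and the classes were 79.4% promoter, 7.17% intron, 4.28% without a listed gene, 3.71% upstream, 1.86% exon, 2.08% downstream and 1.49% TES. The ratios were then 3.97 by promoter and 3.41 by gene body for cell cycle and survival, 2.80 and 2.34 for chromatin regulators, 0 and 0 for myeloid and for hepatocyte genes, and 0 by gene body for olfactory receptors. The share of peaks at a TSS was 75.6% with a window of 5 kb, 67.0% with 500 bp and 70.7% with the deposited promoter class, the last chosen after seeing the data. Hepatocyte genes had a promoter ratio of 0 with a TSS window of 1 kb and with the closest gene only. With a window of 20 kb the ratio was 2.05 for ribosomal protein genes and 0.0424 for olfactory receptors. Without matching on length it was 2.75 for chromatin regulators and 2.13 for ribosomal protein genes by promoter, and 2.35 for cell cycle and survival, 2.22 for chromatin regulators and 1.80 for ribosomal protein genes by gene body. With the closest gene only, also chosen after seeing the data, it was 3.14 for cell cycle and survival and 2.60 for chromatin regulators. With a gene-body flank of 25 kb, likewise chosen later, it was 1.91 for ribosomal protein genes and 0.0758 for olfactory receptors. Except where a setting's construction is named, the cause was not tested. Leaving out the 2 peaks with a fold under 2.2, a setting chosen after seeing the data, moved none of the 14 values compared beyond its interval or limit, and merging peaks within 1 kb moved the number of peaks by less than 1.5 times. No replicate could be left out, and no paired analysis was possible because each group has 1 sample. The planned settings that needed a false discovery rate, summit distances, a flank of 50 kb or the genome sequence were not run. Depth limits what can be said of genes without a peak: the list holds only peaks that passed the caller's threshold, and a weaker site would not be in it.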

Other observations

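The tests in this part were chosen after the result was seen, while the counts of the fixed lists they draw on were planned. Gene families grouped by symbol were counted like the fixed lists. Of the 21 hnRNP genes, which encode RNA-binding proteins of nuclear RNA, 19 had a promoter peak (random mean 7.09, range 3 to 11), and so did 10 of 11 SR splicing factor genes (random mean 3.69, range 1 to 7). Hnrnpab, Hnrnpa2b1 and Hnrnph3 reached scores of 3078.7, 2471.6 and 2438.9. Translation initiation factors (37 of 55, random mean 19.6), mitochondrial ribosomal proteins (48 of 78, random mean 23.9), proteasome subunits (31 of 51, random mean 17.3), RNA polymerase subunits (19 of 28, random mean 9.40), ubiquitin-conjugating enzymes (24 of 37, random mean 13.1), heat shock proteins (13 of 26, random mean 7.58) and chaperonin CCT subunits (8 of 9, random mean 3.24) also lay above the range of random lists. NADH dehydrogenase subunits (21 of 48, random mean 15.3) and the Zfp zinc finger genes (147 of 395, random mean 144) lay within it. Hox genes (0 of 39, random mean 11.5), vomeronasal receptors (0 of 355, random mean 68.3), keratins (1 of 53, random mean 16.5) and potassium channels (11 of 94, random mean 33.0) lay below it.

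Some of the strongest peaks lay away from any listed promoter. The highest without a listed gene were on chromosome 6 from 37682022 to 37683124 (374 tags, fold 41.2, score 2771.4), on chromosome 1 from 88383577 to 88384846 (440 tags, fold 33.2, score 2640.8) and on chromosome 15 from 36809039 to 36810224 (312 tags, fold 36.5, score 2070.3). The peak on chromosome 1 belonged to a run of 5 peaks spanning 41.8 kb up to the Ptma promoter, 4 of them with a fold of 10 or more, which was the most of any run joined at gaps of 20 kb. The peak with most tags in the list, 5070, had the lowest fold, 1.38 (chromosome 11, 3051980 to 3059135).

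The hnRNP promoter peaks had a median score of 596.8, where random sets of 19 promoter-peak genes had a 95% range of 84.7 to 177.6, and the 10 SR peaks had a median of 451.4. Strong promoter peaks were not particular to these families: the median score was also above the random range for the Zfp genes (153.1, range 104.6 to 136.3) and the ubiquitin-conjugating enzymes (178.0, range 88.4 to 171.9). The median fold of the hnRNP peaks was 9.11 (random range 3.93 to 5.32), but score and fold are computed against the same background and the hnRNP family was picked for its scores, so this does not exclude a different background or copy number at these promoters. Transcript abundance alone would also put ribosomal protein genes, whose transcripts are among the most abundant, at the top. Their median score was 119.5, within the random range of 96.9 to 148.1. That rests on the ribosomal protein genes only and no expression values were analysed here, so abundance is not excluded. Background or copy number, transcript abundance, transcription rate as distinct from abundance, base composition and binding of Sox4 itself stay open. No biological explanation was tested because the series has no second condition.

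The 3 B-lineage lists together (V(D)J recombination, transcription factors, pre-BCR and surface genes) had promoter peaks in 37 of 53 genes (69.8%, 55.7 to 81.7%; random mean 18.1, range 12 to 25). Peaks closer to another gene do not account for this. With the closest gene only, 32 of 53 remained against a random mean of 15.4, a count above 100% of random lists. This setting cannot separate genes that share a start, and 751 peaks overlapped the TSS of 2 or more genes. By itself the V(D)J list was then within the random range (6 of 12). The transcription factor list (14 of 22) and the pre-BCR list (12 of 19) stayed above it. The V(D)J list includes end-joining genes such as Xrcc5, Xrcc6 and Nhej1, which are not particular to B cells. Of its members Rag1, Rag2 and Dntt, only Rag1 had a promoter peak. A candidate explanation of the count over the 3 lists is that the peaks mark promoters active in these cells whatever their lineage. Ribosomal protein genes had a promoter peak in 69.8% of cases (58.9 to 79.2%), so by this measure a B-lineage preference and a general preference for active promoters cannot be told apart. What keeps this open is that a pull-down without tagged Sox4 and expression values were not analysed here.

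The low share of chromosome X genes with a promoter peak (7.73%, 6.08 to 9.67%) may in part reflect a single X chromosome, which would halve the reads there and remove weaker peaks. The median tag number of X peaks was 0.79 of the autosomal one. If halving were the whole cause and scores fell in proportion to reads, the X share should approach a share taken from the autosomes. That is the share of autosomal genes with a peak of at least 2 times the lowest score called, a score of 100 or more. It was 20.5% (19.96 to 21.09%). Both the halving and the proportional fall of scores are assumed, and the sex of the cells is not given. This comparison therefore does not decide, and the different gene content of chromosome X was not tested.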
